A study of Polypedilum vanderplanki with 33 samples.

How the data were processed

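Messenger RNA was measured by RNA-seq in whole larvae of the sleeping chironomid Polypedilum vanderplanki, an insect whose larvae survive almost complete desiccation. Per the labels, larvae of inbred lines were dried and then rehydrated, polyadenylated RNA was extracted, and libraries were made with a TruSeq kit. The 33 libraries covered 10 times of dehydration (0, 1, 8, 12, 16, 24, 32, 36, 40 and 48 h) and 7 of rehydration (0, 1, 3, 6, 12, 24 and 48 h). They fell into 2 batches given in the labels, with 22 libraries in batch 1 and 11 in batch 2, and batch 2 held no 0 h or 1 h dehydration library. Samples were grouped by title. A batch 2 library titled as 40 h carried a duration of 48 h, so it was counted at 40 h and moved to 48 h in an alternative.

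The authors deposited counts of reads per gene for 28415 genes, as whole numbers without normalization. Reads were aligned with TopHat2, per the submitters' processing notes, and its version was not given in the sources used here. The authors also deposited the positions of the gene models, an annotation on 6190 scaffolds whose source column names SAJR. The genome build, the counting settings and the use of strand in counting were not given in the sources used here. Overlapping and antisense genes, and genes with a near-identical copy, are therefore uncertain, and 36.2% of the gene models overlapped a neighbour. The count table and the annotation did not pair gene IDs with names, and none of the IDs matched the reference table, which is of assembly Pv_5.2. Positions are given as in the deposited annotation, counted from 1. The gene lists and the heat shock motif test planned before the data were examined needed names or sequence and were not run.

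Total counts lay between 15015674 and 34179203 per library, with a median of 25150715. Intervals and floors cover counting error only. The floor of a gene with no count was taken as 3 counts over all libraries of the group, relative to their total counts, and 95% exact binomial intervals were used for a ratio resting on 1 to 3 counts. Counts of replicate libraries differed by far more than sampling noise in a chi-square comparison over genes with at least 20 counts, so no library was treated as a duplicate of another.

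Genes with a CPM of at least 1 in at least 2 libraries were tested, which left 17846 genes. Differences were tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1) by its quasi-likelihood F-test with robust dispersions, TMM scaling and Benjamini-Hochberg adjustment, at an adjusted p under 0.05. All 33 libraries entered a single fit with a coefficient per time and a batch term, so that times with a single library added to the fit without a test of their own. CPM values in the text are TMM-scaled, except floors and bounds, which use total counts. Log2 CPM values used a prior count of 2. Changes at any replicated time of dehydration were tested jointly. Reversal was tested with Fisher's exact test against the other tested genes. Neighbouring genes were taken as consecutive by start on a scaffold among tested genes, and pairs with both genes up by at least 2-fold were compared with 10000 random reassignments of the calls within 10 bins of mean expression, as a 1-sided permutation test. Since IDs have no names here, the 2 genes with the largest rise and the 2 with the largest fall at 24 h were named, among those past the threshold, changed at least 2-fold, with a mean CPM of at least 5 in the higher group and no overlap between libraries. The 5 longest runs of consecutive genes up at 24 h were named as regions, with ties broken by mean log2 fold change.

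Alternatives were DESeq2 1.42.0, other scaling factors, other count filters, no batch term, batch 1 alone, a replicate block, only the groups compared, a test against a 1.5-fold change, and each library left out in turn. The batch 2 library at 1 h of rehydration stood far from all the others, and the count of genes called in each comparison is also given without it, a choice made after seeing the data. Batch 1 alone leaves this library out as well. The fit was tested on simulated counts of 17846 genes with 200 changed. For 24 h against 0 h with all libraries, 6% of the 4-fold and 45% of the 16-fold changes were recovered with 1 false call, and without the outlying library 39% and 61% with 4. For 48 h against 0 h the shares were 5% and 41%, against 34% and 54% without it. For 3 h against 0 h of rehydration they were 3% and 44%, against 36% and 61% without it. Apart from the planted changes, all simulated libraries of a gene shared the same mean share and dispersion, estimated from the libraries used. The simulated counts thus held no outlying library, and the shares may not hold for the real fit.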

Results

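The series followed gene expression in whole larvae of Polypedilum vanderplanki through a cycle of drying and rewetting. Per the series title, the study concerned the use of the heat shock regulatory system under desiccation. Dehydration was sampled with 2 libraries at 0, 1 and 48 h, 3 at 8, 12, 16, 24 and 40 h, and 1 at 32 and 36 h. Rehydration was sampled with 2 libraries at 0, 1 and 3 h and 1 at 6, 12, 24 and 48 h, and the times with 1 library had no replicate check. Each library held between 15015674 and 34179203 counts. Nothing in the labels says that replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. Genes are given by ID or by scaffold position, since the files do not pair IDs with names.

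Libraries from 8 to 32 h of dehydration resembled each other, and those from 36 h of dehydration to 1 h of rehydration formed a separate block, apart from 1 library. Replicate 2 at 1 h of rehydration, from batch 2, detected 8035 genes, while every other library detected at least 14232. Its highest Pearson correlation with any library, across genes, was 0.694, against at least 0.914 for the other libraries. Counts without it stand beside those of all 33 libraries.

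**Figure D1:**
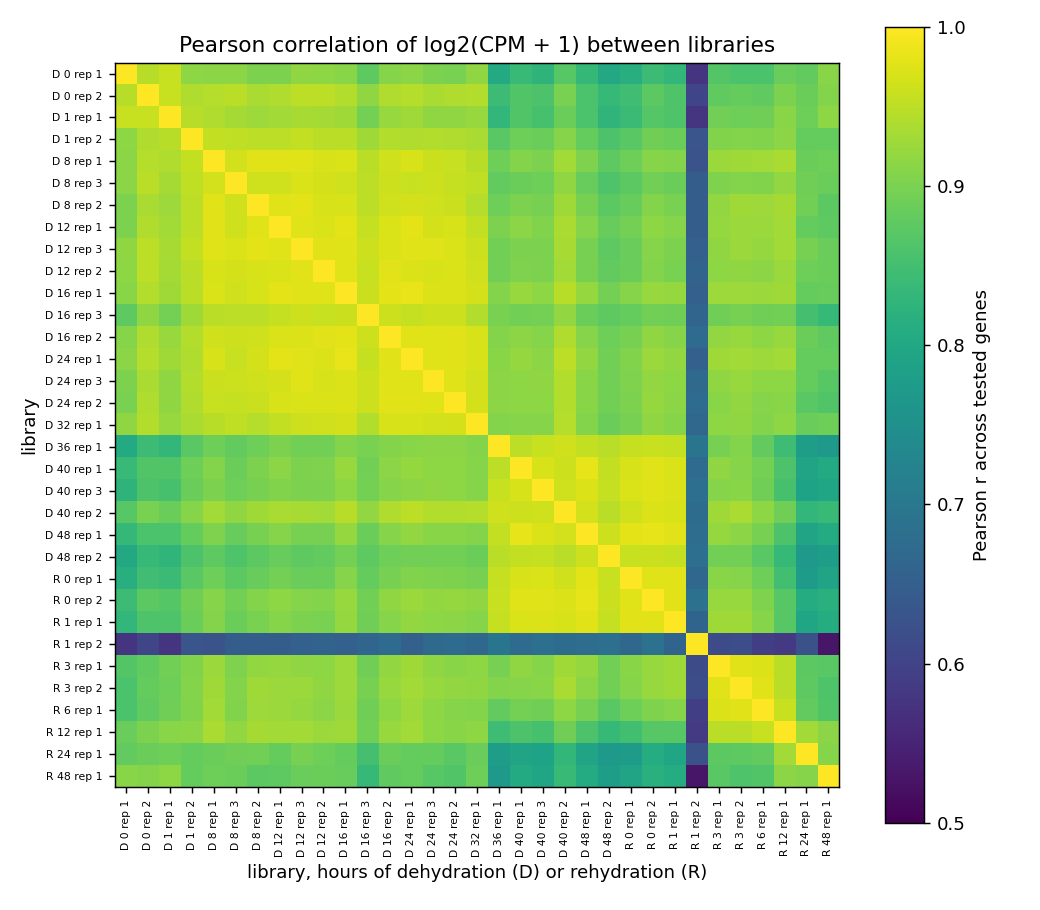
Pearson correlation across the 17846 tested genes, on log2(CPM + 1), between the 33 libraries in order of time, with dehydration (D) and rehydration (R) in hours and replicate (rep) on both axes and the colour giving r. Replicate 2 at 1 h of rehydration reached at most 0.694 with any library.

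The onset of drying was examined at 1 and 8 h against 0 h. At 8 h, region levels were already several times those at 0 h: the 5 gene models of scaffold 77936 (44926 to 49231) summed to 24116 ± 2273 CPM (SD, n = 3) at 8 h and 6042 ± 2231 CPM (SD, n = 2) at 0 h. The 4 genes of scaffold 1028 (331942 to 337161) summed to 686 ± 144 CPM (SD, n = 3) at 8 h and 42.7 ± 36.9 CPM (SD, n = 2) at 0 h. PvG007837 had 0 counts in both 0 h libraries and 16.4 ± 2.24 CPM (SD, n = 3) at 8 h, a rise past the threshold (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0107). The regions and this gene were chosen for their rise at 24 h against the same 0 h libraries, so a low 0 h level was part of the choice. At 8 h, 113 genes rose and 65 fell, and without the outlying library 923 rose and 547 fell. At 1 h, 15 genes rose and 1 fell, and without that library 168 rose and 6 fell.

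The replicates at 1 h lay apart. Across the 169 genes up at 24 h, the median log2 difference from 0 h was 0.05 in replicate 1 and 1.52 in replicate 2, and the scaffold 77936 region summed to 7034 and 18117 CPM. No gene passed at 1 h without 1 h replicate 2, 0 h replicate 1 or 0 h replicate 2, and without 1 h replicate 1 the counts were 21 up and 3 down. At 8 h the counts were 0 up and 1 down without 0 h replicate 1, 22 and 8 without 8 h replicate 1, 16 and 4 without 8 h replicate 2, and 40 down without 8 h replicate 3. Batch 1 alone gave 267 up and 149 down at 8 h and 114 and 8 at 1 h. The share of calls that were up at 8 h was 63.5%, and 51.1% with RLE and 51.5% with upper quartile scaling.

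Between 8 and 24 h the same regions stayed high. At 12 h 107 genes rose and 63 fell against 0 h, and at 16 h 186 rose and 126 fell. Without the outlying library the counts were 736 and 395 at 12 h and 885 and 627 at 16 h. The median log2 difference from 0 h of the 169 genes up at 24 h was between 2.22 and 2.73 in the 12 h libraries and between 2.69 and 3.01 in the 16 h libraries. Without 0 h replicate 1 the counts were 0 up and 2 down at 12 h and 6 up and 4 down at 16 h. Leaving out 12 h replicate 1 gave 31 and 9, replicate 3 gave 65 and 18 and replicate 2 gave 27 down, and leaving out 16 h replicates 1, 2 and 3 gave 119 and 53, 118 and 61, and 86 and 30. The share of up calls at 12 h was 62.9%, and 50.8% with RLE scaling.

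**Figure D2:**
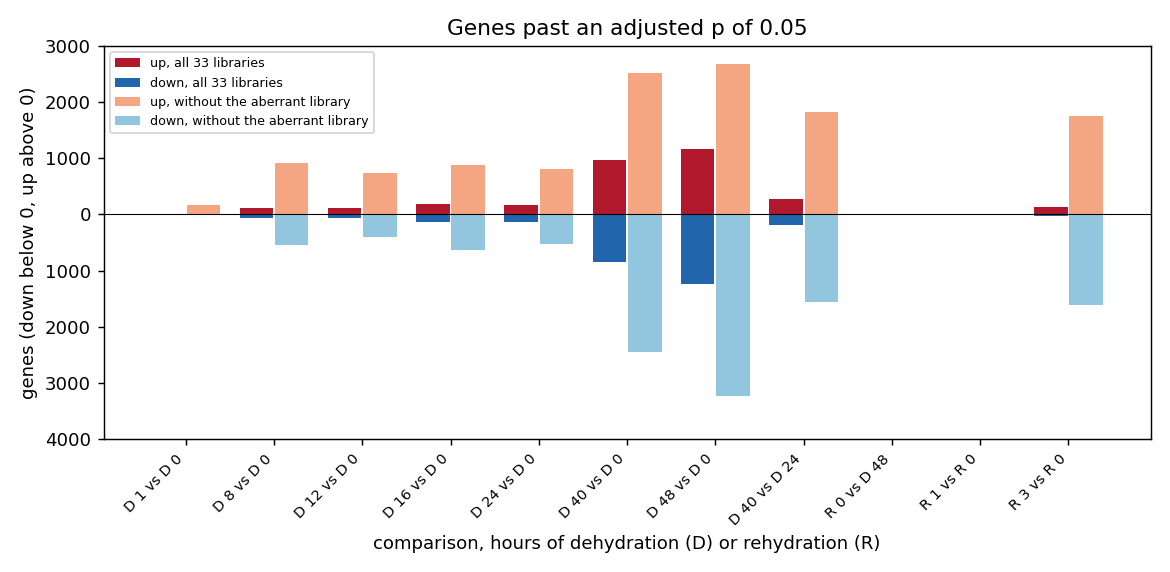
Genes past an adjusted p of 0.05 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) that were up (bars above 0) or down (bars below 0) in each comparison on the x axis, for all 33 libraries (dark) and without the outlying library (pale). At 48 h against 0 h, 1169 genes rose and 1231 fell with all libraries.

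At 24 h, in the middle of drying, the 5 named regions were runs of genes that had each passed at 24 h, so that their rise with all libraries was fixed by how they were chosen. The scaffold 77936 region, with 5 gene models in 4.31 kb, went from 6042 ± 2231 CPM (SD, n = 2) to 28058 ± 2881 CPM (SD, n = 3), with a mean log2 fold change of 2.59 over its genes. The 3 genes of scaffold 331 (93228 to 98047) went from 2452 ± 85.6 to 10642 ± 2613 CPM, the 3 of scaffold 251 (25472 to 27688) from 1010 ± 371 to 5296 ± 92.3 CPM, and the 4 of scaffold 1028 from 42.7 ± 36.9 to 1020 ± 104 CPM. The 4 genes of scaffold 167 (156217 to 159674) went from 4.29 ± 5.73 to 614 ± 227 CPM. Every gene of the 5 regions was also called up without the outlying library, on the same 0 h and 24 h counts. In the scaffold 77936 region 4 of the 5 models overlapped another, as did 2 of 3 on scaffold 251 and 1 of 4 on scaffold 1028, so their reads may be shared.

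The genes with the largest change at 24 h were near absent on one side. PvG007837, on the plus strand of scaffold 167 (156217 to 156909, 2 exons), had 0 counts at 0 h and 2964 over the 3 libraries at 24 h, at least 675-fold higher against a floor of 0.0574 CPM over the 0 h group (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.00258). PvG021343, on the minus strand of scaffold 41978 (2455 to 3538, 2 exons), had 2 counts at 0 h and 5835 at 24 h, a ratio of 1995 with a 95% counting interval of 552 to 16474 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.000601). PvG003247, on the plus strand of scaffold 1230 (204402 to 207751, 5 exons), had 3433 counts at 0 h and 0 at 24 h, at least 1674-fold lower (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.00282). PvG002625, on the plus strand of scaffold 1206 (40 to 541, 3 exons), had 912 counts at 0 h and 0 at 24 h, at least 445-fold lower (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0178). The 24 h libraries differed for PvG007837, with 307 to 2180 counts (9.63 to 64.8 CPM), so its pooled bound leans on the highest of them. The 0 h libraries differed for the falling pair, with 20.2 and 93.9 CPM for PvG003247 and 2.17 and 28.6 CPM for PvG002625. The call of PvG007837 was lost without 0 h replicate 1, and that of PvG002625 without 0 h replicate 1, without any of the 24 h replicates and in batch 1 alone.

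In all, 169 genes rose and 126 fell at 24 h, and each of them was called again, in the same direction, without the outlying library, which gave 817 up and 521 down. That library belonged to neither group, so the fit without it tested the same 0 h and 24 h counts again and is no separate evidence. The 169 genes up took 4.69% ± 1.19 of the counts (SD, n = 2) at 0 h and 18.1% ± 1.41 (SD, n = 3) at 24 h. Leaving out 0 h replicate 1 gave 13 up and 10 down, 24 h replicate 1 gave 105 and 39, replicate 3 gave 93 and 44, and replicate 2 gave 34 down. Batch 1 alone gave 375 up and 244 down, and without the outlying library the counts without 0 h replicate 1 were 354 and 182. The share of up calls was 57.3%, and 48.5% with RLE scaling, which called 147 up and 156 down.

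Genes up at 24 h lay side by side on the scaffolds. Among tested genes, 36 neighbouring pairs were both up, against 2.05 expected, a ratio of 17.6 (1-sided permutation p = 0.0001, the smallest that 10000 reassignments can give). Of the 169 genes, 61 (36.1%) lay in 25 runs of 2 or more, the longest with 5 genes. Pairs that did not overlap gave 22 against 1.40 expected, and pairs more than 1000 bases apart 4 against 0.385 (ratio 10.4, 1-sided permutation p = 0.0002). With calls reassigned within scaffolds 14.7 pairs were expected, and the ratio fell to 2.45 (1-sided permutation p = 0.0001). Without the outlying library 132 pairs were seen against 24.6 expected, a ratio of 5.36, with a longest run of 10 genes. Without 0 h replicate 1, which leaves 1 library at 0 h, few genes were up, and the ratio of 85.5 rests on very few pairs. Genes down at 24 h gave 11 pairs against 0.878 expected, and 44 against 11.4 without the outlying library. At 48 h the ratios were 2.66 for genes up, with 230 pairs, and 2.97 for genes down, with 212 pairs, and for genes up without the outlying library 1.85, with 567 pairs.

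**Figure D3:**
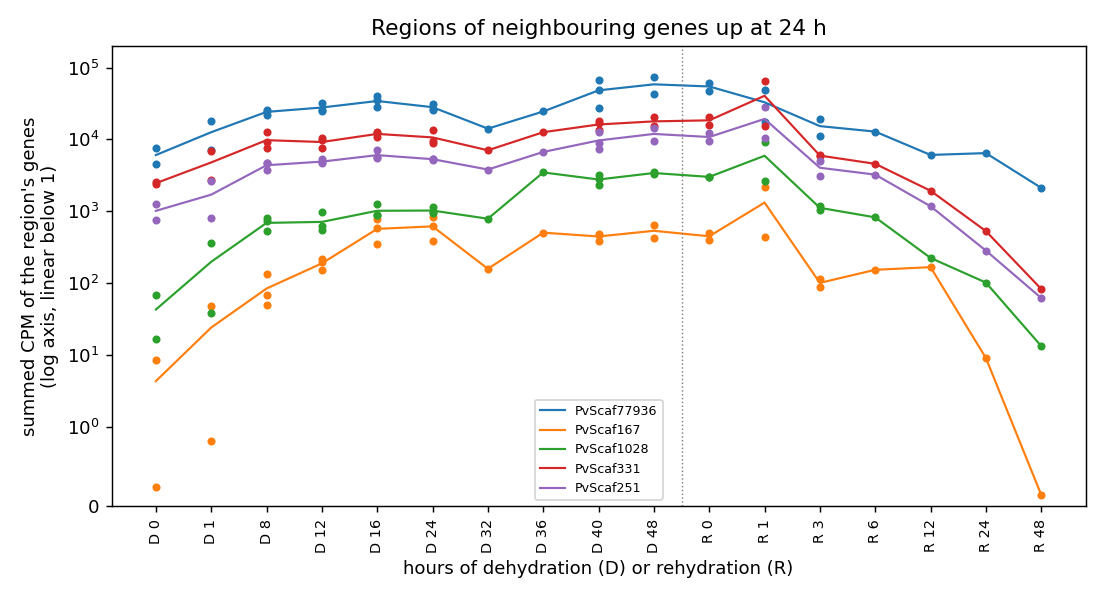
Summed TMM-scaled CPM of the genes of each of the 5 named regions (log axis, linear below 1) against time of dehydration (D) and rehydration (R) in hours, with a point per library and lines through the group means, in a colour per scaffold. The scaffold 77936 region had 6042 CPM at 0 h, 28058 at 24 h, 58389 at 48 h and 15281 at 3 h of rehydration.

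The late phase was examined at 40 h against 24 h and at 48 h against 0 h. By 48 h the scaffold 77936 region stood at 58389 ± 22003 CPM (SD, n = 2), the scaffold 331 region at 17799 ± 3608 CPM, the scaffold 251 region at 11899 ± 3554 CPM and the scaffold 1028 region at 3398 ± 144 CPM, and every gene of the 5 regions was up against 0 h. The scaffold 167 region, at 533 ± 155 CPM, was no higher than at 24 h. Part of the rise from 24 to 48 h in the other regions rests on the TMM factors. These were 0.549 and 0.770 at 48 h against 1.099, 1.06 and 1.047 at 24 h. Of unscaled counts the 5 regions took 0.941% and 1.36% at 0 h. They took 4.62%, 5.52% and 4.47% at 24 h and 6.20% and 5.48% at 48 h, which overlap. Without TMM scaling the scaffold 167 region would lie further below its 24 h level. PvG021343 was at 57.5 ± 3.44 CPM (SD, n = 2), up from 0 h (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 6.87e-05). The 1165 genes up by at least 2-fold at 48 h took 15.4% ± 2.38 of the counts at 0 h, 37.3% ± 1.89 at 24 h and 50.6% ± 0.552 at 48 h.

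At 48 h 1169 genes rose and 1231 fell against 0 h, and without the outlying library 2683 rose and 3233 fell. At 40 h 978 rose and 844 fell against 0 h (2527 and 2440 without that library), and 279 rose and 188 fell against 24 h (1820 and 1559 without it). A joint F-test over the replicated times of dehydration called 1914 genes, and 6017 without that library. With all libraries it called fewer genes than 48 h alone, so it does not count every gene called at some time. All tested genes had a median log2 fold change of -0.21 at 48 h against 0 h, which was -0.41 with RLE and -0.08 with upper quartile scaling, so changes at 48 h are relative to that shift. The share of up calls at 40 h against 0 h was 53.7%, and 42.8% with RLE scaling.

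At 48 h the counts were 477 up and 665 down without 0 h replicate 1, 715 up without 0 h replicate 2, 730 up without 48 h replicate 1, and 737 up and 305 down without 48 h replicate 2, and batch 1 alone gave 2043 up. For 40 h against 24 h, leaving out 24 h replicates 1, 2 and 3 gave 55 and 42, 71 and 50, and 58 and 45, leaving out 40 h replicates 1 and 3 gave 99 and 29 and 109 and 35, and leaving out 40 h replicate 2, the library with conflicting durations, gave 242 and 439. Batch 1 alone gave 1275 up and 1844 down for 40 h against 24 h. In batch 1 alone 48 h was a single library. For 40 h against 0 h the counts were 311 and 313 without 0 h replicate 1, 555 and 549 without 0 h replicate 2, 376 down without 40 h replicate 1 and 373 down without replicate 3. Moving the library with conflicting durations to 48 h gave 779 down at 48 h and 290 down for 40 h against 24 h.

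Genes called at 24 h were mostly called at 48 h too. Of the 169 up at 24 h, 163 were up at 48 h, against 11.1 for independent lists, and of the 126 down, 91 were down, against 8.69. None of these was called in the opposite direction at 48 h. In the fit without the outlying library, 726 of the 817 genes up at 24 h were up at 48 h (123 for independent lists) and 9 were down, and 386 of the 521 down were down (94.7) and 4 were up. Both comparisons used the same 2 libraries at 0 h, which were not split between them, so part of the excess may come from sharing them. In counts simulated with no changed gene and the same shared libraries, 0 genes were called at 24 or 48 h and 0 overlapped. With no gene called, that simulation does not show how far sharing adds to the overlap of real calls.

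The step between the early and the late phase lay between 32 and 36 h in batch 2, where those times were sampled with 1 library each. The median log2 difference from 0 h of the 1165 genes up at 48 h was 0.94 at 24 h in replicate 2, 0.83 at 32 h and 2.36 at 36 h, all of batch 2. For the 1231 genes down at 48 h it was -0.78, -0.63 and -2.30. Across genes, the 32 h library had a Pearson correlation of 0.968 with 24 h replicate 2 and 0.907 with the 36 h library, which in turn had 0.964 with 40 h replicate 2. The 1165 genes took 26.0% of the counts at 32 h, below the 35.8% of 24 h replicate 2 and the 49.6% at 36 h. The scaffold 77936 region, at 14094 CPM, also lay below the 26818 CPM of 24 h replicate 2 and the 24438 CPM at 36 h. The place of the step thus leans on a single library that lay below both in these levels.

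**Figure D4:**
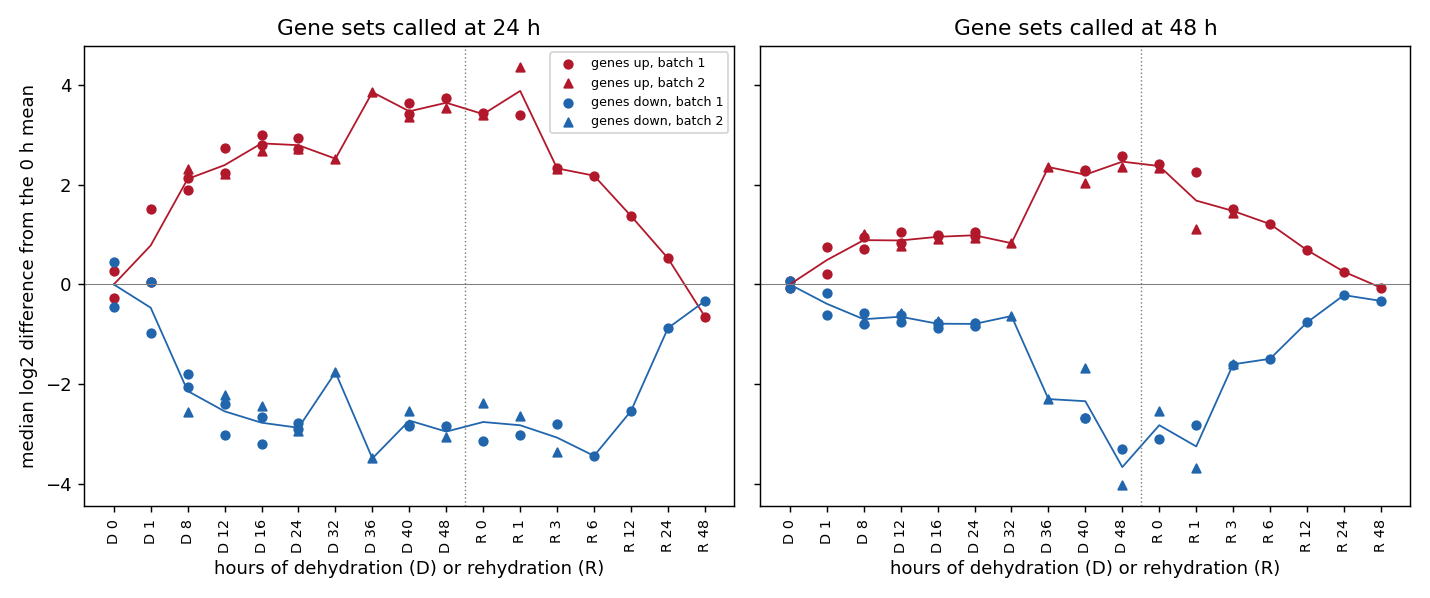
Median log2 difference from the 0 h mean, over genes up (red) or down (blue) by at least 2-fold at 24 h (left panel) or 48 h (right panel), in each library (circles batch 1, triangles batch 2) against hours of dehydration (D) and rehydration (R), with lines through group means. The genes were chosen on the 0 h and 24 h or 48 h libraries. The set up at 48 h had a median of 0.83 at 32 h, 2.36 at 36 h and -0.07 at 48 h of rehydration.

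The start of rehydration was compared with the end of dehydration. Levels at 0 h of rehydration were close to those at 48 h of dehydration: the scaffold 77936 region had 54507 ± 9506 CPM (SD, n = 2) against 58389 ± 22003 CPM, and the scaffold 1028 region 3000 ± 43.1 against 3398 ± 144 CPM. PvG021343 had 193 ± 35.0 CPM (SD, n = 2) against 57.5 ± 3.44 CPM and did not pass. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 genes rose and 0 fell, with 567 genes at an unadjusted p under 0.05, where chance alone would give 892, and without the outlying library 1135. DESeq2 called 7 up and 2 down, and without the outlying library edgeR called 1 up and 0 down at the adjusted threshold. Leaving out 48 h replicate 1 gave 33 up, or 628 up and 50 down without the outlying library as well.

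Rewetting was followed at 3 h against 0 h of rehydration, when the summed levels of the regions were lower, though most of their genes did not pass. The scaffold 77936 region had 15281 ± 5790 CPM (SD, n = 2) at 3 h against 54507 ± 9506 CPM at 0 h, the scaffold 331 region 5940 ± 58.9 against 18394 ± 3258 CPM, the scaffold 251 region 4020 ± 1376 against 10774 ± 2017 CPM, and the scaffold 1028 region 1112 ± 96.6 against 3000 ± 43.1 CPM. The scaffold 167 region had 100 ± 17.3 against 446 ± 72.2 CPM. The median log2 fold change per region lay between -1.88 and -1.38. Part of the fall rests on the TMM factors, 0.627 and 0.645 at 0 h against 1.12 and 1.29 at 3 h. Of unscaled counts the 5 regions took 5.83% and 5.24% at 0 h and 3.53% and 2.74% at 3 h. Of the 19 genes of the 5 regions, 3 fell, all on scaffold 77936, and 7 fell without the outlying library, with 4 on scaffold 77936, 2 on scaffold 251 and 1 on scaffold 331. No gene of the scaffold 1028 or 167 region passed in either fit. PvG021343 had 36.7 ± 2.77 CPM at 3 h and did not pass (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.201). Over all genes 139 rose and 33 fell, and without the outlying library 1750 rose and 1609 fell.

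At 1 h of rehydration 2 genes rose and 2 fell against 0 h, and none of these was called without replicate 2, when edgeR called 1 up and 0 down. DESeq2 called 828 up and 255 down with replicate 2 included. At 3 h the counts were 1 up and 0 down without either 0 h replicate, 8 and 0 without 3 h replicate 1, and 22 and 1 without 3 h replicate 2, and at 1 h they were 0 up and 1 down without 0 h replicate 1 and 0 and 0 without 0 h replicate 2. Batch 1 alone held 1 library at 0 h and 1 at 3 h of rehydration and left out the outlying library, so it was no replicated check. The share of up calls at 3 h was 80.8%, and 57.5% with upper quartile scaling, and without the outlying library 52.1% and 39.9%.

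Genes changed by drying changed back more often than the other genes. Of the 1169 genes up at 48 h of dehydration, 22 (1.88%) fell by 3 h of rehydration, against 0.0660% of the other genes, an odds ratio of 29.1 (95% interval 13.5 to 66.5, two-sided Fisher's exact test p = 7.26e-19). Of the 1231 down at 48 h, 59 (4.79%) rose, against 0.481% of the others, an odds ratio of 10.4 (95% interval 7.26 to 14.8, two-sided Fisher's exact test p = 3.70e-32). Without the outlying library 996 of 2683 genes up (37.1%) fell again, against 4.06% of the others, an odds ratio of 14.0 (12.5 to 15.6), and 944 of 3233 genes down (29.2%) rose again, against 5.54%, an odds ratio of 7.03 (6.33 to 7.82). Of the genes up at 48 h of dehydration, 5 rose further by 3 h of rehydration, and of those down, 2 fell further. The dehydration and rehydration comparisons shared no library, but all libraries entered the same fit. Each gene's dispersion and the batch term were thus common to both, which may add to the overlap of calls. How far it does was not tested. Genes are also not independent replicates, so the Fisher p-values overstate the evidence. With all libraries the share of genes up that fell again was 0% without 3 h replicate 2, and the share of genes down that rose again was 0% without either 0 h rehydration replicate, where at 3 h a single gene was called in the direction counted.

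Recovery continued to 48 h, in single libraries of batch 1. The median log2 difference from 0 h of dehydration of the 169 genes up at 24 h was 2.19 at 6 h of rehydration, 1.38 at 12 h, 0.53 at 24 h and -0.65 at 48 h, while the 0 h libraries lay at -0.27 and 0.27. The scaffold 331 region had 1922 CPM at 12 h, 527 at 24 h and 82.4 at 48 h. The scaffold 167 region did not fall steadily. It had 100 CPM on average at 3 h, 152 CPM at 6 h, 166 CPM at 12 h and 0.144 CPM at 48 h. Its gene PvG007837 had 3.14 CPM on average at 3 h, 4.99 at 6 h, 21.6 at 12 h and 3.62 at 24 h. At 48 h of dehydration PvG007837 had 15.5 ± 5.20 CPM (SD, n = 2). PvG021343 had 21.0 CPM at 12 h, 5.32 at 24 h and 1.30 at 48 h. PvG003247 had 0 counts at 6 and 12 h, 14.1 CPM at 24 h and 84.6 CPM at 48 h. PvG002625 was at 0.756 CPM at 48 h.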

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

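The tests for a wrong label at 1 h of rehydration and at 1 h of dehydration were chosen only after the result was seen. The single libraries at 24 and 48 h of rehydration entered no comparison, and each held genes far above all other samples. In them, 7 genes at 24 h and 29 at 48 h had at least 10 CPM and at least 4 times the CPM of every other library. The 0 h dehydration libraries held at most 3 such genes, but each has a replicate at its time, so they are no like comparison. The single libraries at 32 and 36 h of dehydration and at 6 and 12 h of rehydration held 0, and the outlying library held 197.

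Replicate 2 at 1 h of rehydration stood apart from every other library. Its best Pearson correlation was 0.694, below the 0.914 that every other library reached. This argues only against an otherwise intact library of the series under a wrong label. The library was singled out by this value, and a loss of transcripts would lower it under any label. A swap or a wrong label therefore stays open. A small number of starting molecules alone is argued against by the SD of 2.58 of the log2 ratio to replicate 1 over 71 genes of at least 2000 CPM, against 0.271 between the 0 h rehydration replicates. A loss of long transcripts may contribute, since across 1118 genes the log2 ratio had a Spearman rho of -0.746 with exonic length, against -0.19 between the 0 h rehydration replicates, and genes are not independent replicates. What led to such a loss stays open, and no biological explanation was tested since the replicates share a group.

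The dehydration replicates at 1 h lay apart by the genes up at 24 h. Replicate 2 had a median log2 rise of 1.52, below the 1.90 to 3.01 of the libraries of 8 to 24 h, by less than the range of 0.54 of the 0 h libraries, so a library of later time with a wrong label cannot be told apart from a faster response. A difference between larvae in the speed of drying may be another explanation, and it was not tested.

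Neighbouring genes were up together at 24 h. Reads shared by overlapping models are argued against as the whole cause by a ratio of 15.7 among pairs that do not overlap. A concentration on gene-dense scaffolds is argued against as the whole cause by a ratio of 2.45 with calls reassigned within scaffolds. That run expected 14.7 pairs where 36 were seen, against 2.05 expected in the main test. Such a concentration may thus account for part of the excess. The run reassigned calls within scaffolds and not within bins of expression. Reads shared between near-identical copies cannot be told apart from joint regulation, since no sequence of these genes was used here and pairs more than 1000 bases apart, at a ratio of 10.4, could also be copies. Joint regulation of neighbours stays open as a hypothesis.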

How the results depend on the processing

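Removing the outlying library and every test combined with it were chosen after seeing the data, as were the neighbour tests on pairs that do not overlap or lie over 1000 bases apart. Apart from leaving out libraries, 328 alternatives were run over all results, and 233 kept the verdict (counts within 1.5 times), 94 counts moved further and 1 call was lost, that of PvG002625 in batch 1 alone. The 328 include alternatives run without the outlying library and judged against the fit without it. The 233 are thus not all agreements with the planned fit. The neighbour ratio without a fold threshold could not differ, since all 169 genes up at 24 h had changed at least 2-fold. None of the 328 reversed, and the shares changed back went to 0 in 3 runs without a library, where 3 h of rehydration called 1 gene in the direction counted. The cause was not tested unless stated. The gene lists, the motif test, and, for genes changed over dehydration, the test against a 1.5-fold change and the fit of only the groups compared were not run. The neighbour ratio of genes up at 24 h was past the threshold in these 8 alternatives, between 5.36 and 25.3, and in the runs without 1 library, between 16.4 and 85.5, the highest on very few pairs. It was 2.45 with calls reassigned within scaffolds, and 4.94 for pairs over 1000 bases apart without the outlying library. Depth limits genes near the floor.

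Pairs of numbers are up then down, in the order 1, 8, 24 and 48 h against 0 h, 40 against 24 h, 0 h of rehydration against 48 h, and 3 h against 0 h of rehydration. DESeq2 gave 141 and 12, 440 and 326, 411 and 364, 2957 down, 720 and 1123, 7 and 2, 1177 and 356, and 4362 changed over dehydration. Without the outlying library the counts were 168 and 6, 923 and 547, 817 and 521, 2683 and 3233, 1820 and 1559, 1 up, 1750 and 1609, and 6017 over dehydration, with 736 and 395 at 12 h, 885 and 627 at 16 h, 2527 and 2440 at 40 h, and 1 and 0 at 1 h of rehydration. Batch 1 alone gave 114 and 8, 267 and 149, 375 and 244, 2043 up, 1275 and 1844, 785 and 328 at 3 h, and 4231 over dehydration. In batch 1 alone, 48 h of dehydration and 0 and 3 h of rehydration held 1 library each, and the outlying library was absent. The 2 groups alone gave 8 and 0, 45 and 13, 211 down at 24 h, 1739 and 1304, and 1811 and 1684 at 3 h. Testing against a 1.5-fold change gave 9 and 0, 45 and 27, 108 and 73, 92 and 55, and 49 and 2 at 3 h, by construction fewer. The conflicting library at 48 h gave 779 down at 48 h and 290 down at 40 h against 24 h. Without a count filter, 1 h gave 0 down, 40 against 24 h 150 and 119, 3 h of rehydration 8 down and 1 h of rehydration 0 down. The stricter filter gave 126 down at 8 h, 326 down at 40 against 24 h, and 309 and 212 at 3 h of rehydration. RLE scaling gave 250 up and upper quartile scaling 124 down at 3 h of rehydration. Without a batch term, 1 h gave 0 down and 1 h of rehydration 1 up.

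The replicate block gave 0 down at 1 h, 294 and 127 at 8 h and 305 up at 24 h, with its counts for the other comparisons in the order above and for dehydration as a whole within 1.5 times. For 12, 16 and 40 h against 0 h and for 1 h against 0 h of rehydration, the replicate block, batch 1 alone, the groups alone, the stricter filter, the conflicting library at 48 h and the 1.5-fold test are not reported here. Whether the numbers pair the samples is not settled. Same-numbered deviations correlated at -0.07 to 0.15 over 45 pairs for number 1 and 0.03 to 0.13 over 10 for number 3. The 1 pair for number 2, at 0.13, mirrors the pair of number 1 at the same times, where each group held 2 libraries. It is no separate evidence. All 10 of the 10 libraries of 8 to 40 h numbered 1 or 3 lay closer to their own number, a hint from the data, not the design.

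Leaving out each library, where a lone one is assumed to vary like the other groups, gave 0 to 21 up and 0 to 3 down at 1 h, 0 to 91 and 1 to 84 at 8 h, 0 to 102 and 2 to 82 at 12 h, 6 to 148 and 4 to 109 at 16 h, 13 to 149 and 10 to 119 at 24 h, 311 to 904 and 313 to 1071 at 40 h, 477 to 737 and 305 to 1239 at 48 h, 55 to 242 and 29 to 439 at 40 against 24 h, 0 to 33 and 0 to 0 at 0 h of rehydration against 48 h, 1 to 22 and 0 to 1 at 3 h of rehydration, and 0 to 0 and 0 to 1 at 1 h of rehydration. The lowest counts at 8, 12, 16 and 24 h came without 0 h replicate 1. The shares changed back ran from 0 to 2.85% for genes up and 0 to 14.4% for genes down, and no share was computed where 3 h against 0 h of rehydration called no gene. Without the outlying library, 24 h gave 354 to 807 up and 182 to 499 down, and 48 h 1986 to 2447 and 1984 to 3660.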

Other observations

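The counts of genes and regions above or below the 0 h level, the levels of the 32 h library and the tests without the outlying library or on pairs more than 1000 bases apart were chosen only after the result was seen. After 48 h of rehydration, many genes that rose with drying lay below their starting level. In that single library, 91 of the 169 genes up at 24 h of dehydration were below both 0 h libraries, and so were all 5 of the 5 named regions. Of the 169, 76 were over 2-fold below the 0 h mean and 35 over 2-fold above. The share of all tested genes below both 0 h libraries was not computed, so the 91 have no chance value beside them. The scaffold 331 region had 82.4 CPM at 48 h of rehydration against 2452 ± 85.6 CPM (SD, n = 2) at 0 h, and the scaffold 251 region 61.6 against 1010 ± 371 CPM. PvG003247, which fell at 24 h, had 84.6 CPM against 57.0 ± 52.1 CPM (SD, n = 2).

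The 32 h library held the highest level of its most abundant gene, 73122 CPM of total counts, against 1812 on average at 0 h and at most 23352 in any other library, replicate 2 at 0 h of rehydration.

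A return to the starting level was tested as a hypothesis on the genes up at 48 h of dehydration, whose median log2 difference from 0 h was -0.0653 in the 48 h rehydration library, within the range of -0.0757 to 0.0757 of the 0 h libraries. Its members went both ways, 182 of 1165 being over 2-fold above and 225 over 2-fold below the 0 h mean, so this median does not show a return. The genes down at 48 h had a median of -0.33, outside the range of -0.07 to 0.07 of the 0 h libraries. The genes down at 24 h were also tested for lying together, and their neighbouring pairs were 12.5 times those expected (1-sided permutation p = 0.0001, the smallest that the reassignments can give). The ratio was 3.86 without the outlying library, and among pairs more than 1000 bases apart 2 pairs were seen with all libraries (1-sided permutation p = 0.0159). An excess of single-exon genes among those up at 24 h was not shown, with an odds ratio of 1.197 (95% interval 0.777 to 1.79, two-sided Fisher's exact test p = 0.390), and without the outlying library it was 0.751 (0.579 to 0.962).

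For 40 h against 24 h, the 6 libraries allow 10 splits, too few for a share under 0.05. The real split was the 1 split with the most calls, 467 genes, and the highest of the other splits gave 0.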
